A study of Mus musculus with 21 samples.

How the data were processed

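RNA was measured by sequencing in 21 mouse libraries: MEF (2), day 12 (1), day 16 (2), day 20 (1), day 26 (1), day 28 (1), CeXEN (2), eXEN (2), ESC (2) and CiPSC (7, 1 per line). Total RNA was extracted with RNeasy kits and libraries were made with NEBNext Ultra kits, per the labels. The deposited files hold FPKM values, 1 file per library, made by the authors with TopHat and Cufflinks on the mouse genome mm10 according to the submitters' processing notes, with versions and gene model release not given. Each file lists 43496 loci with 43437 Ensembl gene IDs, of which 43436 are in every file, and 41 IDs have several loci, whose FPKM values were added. Coordinates are mm10, counted from 1. Of the IDs that passed the filter on low values given below, 98.7% were found in the reference annotation used for gene classes. The status column of the quantifier is not OK in at least 1 library for 472 genes, 78 of them tested, and these were kept. Read counts and raw reads were not used here.

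Values were analysed as log2(FPKM + 1), which understates changes of genes with low FPKM, so that fold changes near 0 FPKM are not read as ratios. Genes with an FPKM of at least 1 in at least 2 libraries were tested (16650 genes). All 21 libraries entered a single linear model with 1 coefficient per group (11 residual degrees of freedom), fitted with limma 3.58.1 in R 4.3.3 with an intensity trend of the prior variance, and p-values were adjusted by Benjamini-Hochberg within each comparison. The single libraries of day 12, day 20, day 26 and day 28 add no residual degrees of freedom, and where a leave-out left 1 library in a group, that library was assumed to vary like the other groups. A gene was called at an adjusted p under 0.05 and an absolute log2 change of at least 1. The 6 comparisons were day 16 against MEF, eXEN against ESC, day 16 against eXEN, CeXEN against eXEN, CiPSC against day 16 and CiPSC against ESC. A linear trend on the day was fitted to the 6 libraries from day 12 to day 28 and is given as the change over 16 days. Group means are in FPKM with the SD over libraries, and changes are log2 differences with the SE of the fit.

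30 lists of marker and pathway genes were written by hand and tested with camera in limma, with a preset correlation between genes of 0.01 and, as alternatives, an estimated correlation and the rotation test fry, which tests a list against no change rather than against the other genes. List p-values were adjusted over the 30 lists of a comparison, and members were also adjusted over the list alone. Reference signatures were taken from contrasts of MEF, ESC and eXEN in the fit of all libraries, as genes called with a log2 change of at least 2 against each of the other 2 groups. Their medians were placed on a scale from 0% to 100% between reference groups. Genes were named by a fixed rule: 12 markers always, the 5 highest and 5 lowest changes among called genes whose groups do not overlap and with a mean FPKM of at least 5 in 1 group (predicted genes, clone names and small RNAs left out), and up to 4 called members with the largest change in each described list, of which some are given. Some genes that the rule names are not reported here. The gene lists, comparisons, thresholds, naming rule and first set of alternatives were chosen before the data were examined.

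Sequencing depth was estimated from genes of low FPKM, where the bounds of the quantifier give the number of fragments behind a value, and is relative to ESC replicate 1: 0.4 to 1.58 over all libraries, 1.09 and 1.18 for day 16, and 1.5 and 0.82 for CeXEN. The model was tested on simulated data with the same spread and 200 changed genes of 16650, and found 74% to 92% of changes of 2 log2 units in the comparisons of groups and 6% in the trend. Alternatives covered the pseudocount (0.1), filters on low values (none, or FPKM 5), scaling (quantile normalization, median-of-ratios), the fit (only the groups compared, no intensity trend with a robust prior, the replicate number as a block), genes with status OK alone, X and Y genes left out, the rank of the day, and each replicate left out. Further alternatives were chosen after seeing the data: protein-coding genes of at least 1000 nt without an annotated selenocysteine, the processing set of the time course libraries as a covariate or 4 of these libraries alone, the level of the fibroblast list as a covariate, and list tests with a replicate block or without single day 16 libraries. Other tools were statmod 1.5.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.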

Results

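RNA from 21 mouse libraries in 10 groups was sequenced, and expression was given as FPKM, the fragments mapped to a gene scaled by its length and by the fragments of the library. The series follows chemical reprogramming, in which small molecules rather than introduced genes turn somatic cells into pluripotent cells. The starting cells were embryonic fibroblasts (MEF) taken at mid-gestation, with 2 libraries. Cells on the way were taken at day 12, day 20, day 26 and day 28, with 1 library each and hence no replicate, and at day 16, with 2 libraries. The end products were 7 chemically induced pluripotent stem cell (CiPSC) lines named C1, C2, C3, G1, G3, N4 and N6, with 1 library each. Embryonic stem cells (ESC) from embryonic day 3.5 served as the pluripotent reference, with 1 library from the reporter strain of the fibroblasts and 1 from C57BL/6 (B6)N. Extraembryonic endoderm (XEN) cells, which derive from the primitive endoderm of the blastocyst, came from 2 sources. An established XEN line (eXEN) gave 2 libraries, of which replicate 1 was kept in the chemical medium of the first reprogramming stage with 20 ng/ml bFGF and replicate 2 in conventional XEN medium. XEN cells derived from embryonic day 3.5 embryos in that chemical medium with 20 ng/ml bFGF (CeXEN) gave 2 libraries. All XEN libraries are wild-type ICR, whereas MEF, the cells on the way and CiPSC carry the reporter strain crossed with ICR. Neither ESC library is wild-type ICR. Strain and cell type therefore cannot be separated when XEN cells are compared with cells on the way, MEF or ESC. Xist, expressed from the inactive X chromosome, stood at 0.00358 and 4.2 FPKM in MEF, 4.15 and 22.7 at day 16, 5.74 and 8.41 in CeXEN and 0.00347 and 0.00330 in eXEN, so the sex of the cells may not be balanced either.

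The values are normalised, so read counts per library are not known. The sum of FPKM ranged from 543198 in MEF replicate 2 to 864945 in CeXEN replicate 2, and 11240 genes in eXEN replicate 2 to 13982 genes at day 12 had an FPKM of at least 1. The FPKM of a single fragment, read from genes with 1 fragment, put sequencing depth between 0.4 times (CiPSC line C3) and 1.58 times (CiPSC line N4) that of ESC replicate 1. Replicates correlated across genes at r = 0.935 for day 16, 0.94 for MEF, 0.953 for CeXEN, 0.952 for eXEN and 0.959 for ESC, and CiPSC lines at 0.943 to 0.981, where genes are not independent replicates. Day 16 replicate 1 correlated more with day 12 (0.946), day 20 (0.975), day 26 (0.97) and day 28 (0.948) than with day 16 replicate 2. Day 16 replicate 2 stood at 0.94 with day 12, 0.93 with day 20, 0.929 with day 26 and 0.91 with day 28. Mitochondrial transcripts took 0.58% (CiPSC line C3) to 4.44% (day 16 replicate 2) of the FPKM, with 3.73% ± 0.11 (SD, n = 2) in ESC and 1.17% ± 0.49 (SD, n = 7) in CiPSC. The labels do not say whether replicates were separate cultures, so the adjusted p-values measure the spread between these samples, be it biological or technical. That spread was estimated over all groups together, and the CiPSC lines (n = 7) gave most of its residual degrees of freedom. The p-values of a comparison of other groups therefore do not measure the spread of those groups alone.

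The established XEN line and ESC are the reference states, and their comparison shows which genes separate them. XEN cells held the mRNA of endoderm transcription factors and large amounts of basement membrane mRNA, and little of the pluripotency factors. Gata4, a GATA factor of endoderm, stood at 472 ± 67.4 FPKM (SD, n = 2) in eXEN and 1.14 ± 0.605 FPKM (SD, n = 2) in ESC, a log2 change of 7.81 ± 0.34 (SE, adjusted p = 1.17e-09). Pou5f1 (Oct4, ENSMUSG00000024406, mm10 chromosome 17, positions 35506018 to 35510772), the core pluripotency factor, stood at 0.676 ± 0.623 FPKM and 658 ± 146 FPKM, a log2 change of -8.65 ± 0.28 (SE, adjusted p = 8.46e-11).

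Of the 20 measured transcription factors and signalling genes of the XEN list, 15 rose and 2 fell in eXEN (15 and 2 adjusted over the list alone). The XEN regulator list had a median log2 change of 4.03 and an adjusted p of 3.96e-13. Beside Gata4, the endoderm regulators Sox7 (6.93), Foxa2 (6.67), Sox17 (6.66) and Gata6 (6.22) rose on the log2 scale. Of 21 measured parietal endoderm and basement membrane genes, 18 rose (18 adjusted over the list alone). The parietal endoderm list had a median log2 change of 4.23 and an adjusted p of 6.55e-18. The laminin chain Lama1 rose by 8.13 ± 0.57 to 1754 ± 1178 FPKM, the laminin chain Lamb1 by 6.98 ± 0.42 to 2805 ± 1950.4 FPKM, and the parathyroid hormone receptor Pth1r, a parietal endoderm marker, by 7.0 ± 0.52. The water channel Aqp8 (8.51) and the ligand Wnt11 (7.28) completed the largest increases, and the activin antagonist Fst (6.29) rose as well. Lin28a, an RNA-binding protein of early embryonic cells, was higher in eXEN (2.01 ± 0.37 SE, adjusted p = 0.000754), and Sall4, a zinc finger factor shared by early lineages, did not pass the test (-0.61 ± 0.33 SE, adjusted p = 0.162). Genes that respond to cyclic AMP were higher, with 6 of 18 rising and 1 falling (6 and 1 adjusted over the list alone). The cAMP target list had a median log2 change of 0.63 and an adjusted p of 0.00377 (adjusted p = 0.0892 with an estimated correlation, 0.000173 to 0.0892 over the alternatives). cAMP target genes included the stress-responsive factor Atf3 (3.53) and the early response gene Fosb (3.08).

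Of 38 measured pluripotency genes, 32 fell in eXEN and 1 rose (35 and 1 adjusted over the list alone). The pluripotency list had a median log2 change of -5.23 and an adjusted p of 1.1e-17. Dppa5a fell by 9.86, the Nodal co-receptor Tdgf1 by 8.46, Nanog by 8.44 and Sox2 by 7.51 on the log2 scale, with ESC levels of 433 ± 75.9 FPKM for Nanog and 206 ± 13.9 FPKM for Sox2. The small heat shock protein Hspb1 was the other gene among the largest decreases (-8.33 ± 0.37 SE, adjusted p = 1.27e-09). Germ cell genes were low in eXEN: 17 of 22 fell (18 adjusted over the list alone). The germ cell list had a median log2 change of -3.12 and an adjusted p of 1.11e-07 (adjusted p = 0.503 with an estimated correlation, 3.41e-12 to 0.503 over the alternatives). Germ cell genes included the RNA-binding protein Dazl (-6.53) and the meiotic protein Hormad1 (-5.05). Of 18 genes of two-cell-like cells, 9 fell (17 adjusted over the list alone). The two-cell-like list had a median log2 change of -1.81 and an adjusted p of 0.00337 (adjusted p = 0.827 with an estimated correlation, 1.86e-09 to 0.827 over the alternatives). Zscan4f stood at 45.8 ± 28.0 FPKM in ESC and 0.0994 ± 0.0618 FPKM in eXEN. Zscan4 genes are near-identical copies of each other, so their single values are uncertain. Epithelial genes fell more often than they rose, 12 against 2 of 24 (12 and 2 adjusted over the list alone). The epithelial list had a median log2 change of -1.26 and an adjusted p of 0.0398 (adjusted p = 0.827 with an estimated correlation, 0.00248 to 0.827 over the alternatives). The adhesion protein E-cadherin (Cdh1) fell by 6.62 and the serine protease inhibitor Spint2 by 6.11 on the log2 scale. Cell cycle genes were lower by less, 13 of 28 falling (13 adjusted over the list alone). The cell cycle list had a median log2 change of -0.99 and an adjusted p of 0.000953 (adjusted p = 0.827 with an estimated correlation, 1.21e-05 to 0.827 over the alternatives). Cell cycle genes included the cyclin Ccnb2 (-1.27).

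In all, 1628 genes were higher and 3057 lower in eXEN, a share of 34.7% higher, and 996 and 2256 in a fit of only these 2 groups. The median gene differed by -0.258 on the log2 scale as deposited, by 0.02 after quantile normalization and by -0.17 after median-of-ratios scaling, and with quantile normalization the split was 2347 higher and 2130 lower (52.4% higher).

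Day 16 against MEF asks which genes changed between the starting fibroblasts and the replicated time point on the way. By day 16 the cells expressed endoderm regulators that were near absent in fibroblasts, had gained epithelial genes and had lost most fibroblast matrix mRNA, while Pou5f1 and Nanog did not pass the test. The epithelial and fibroblast lists did not pass with an estimated correlation (adjusted p = 0.0948 for each). Sox17 (ENSMUSG00000025902, mm10 chromosome 1, positions 4490931 to 4497354), an endoderm factor, stood at 516 ± 119 FPKM (SD, n = 2) at day 16 and 0.105 ± 0.149 FPKM (SD, n = 2) in MEF, a log2 change of 8.86 ± 0.33 (SE, adjusted p = 5.94e-10). Gata4 stood at 413 ± 61.1 FPKM and 0.221 ± 0.270 FPKM (8.42 ± 0.34 SE, adjusted p = 7.61e-10), and collagen I chain Col1a1 at 58.5 ± 46.2 FPKM and 3063 ± 2257 FPKM (-5.72 ± 1.20 SE, adjusted p = 0.00259).

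Of 20 measured XEN regulators, 16 rose and 1 fell (16 and 1 adjusted over the list alone). The XEN regulator list had a median log2 change of 3.64 and an adjusted p of 1.61e-11. The transcriptional co-regulator Cited1 rose by 9.10 ± 0.57, the signalling protein Ihh by 6.69 ± 0.37, Foxa2 by 5.99 ± 0.26 and Gata6 by 4.01 ± 0.47. The largest increases were the calcium-binding protein S100g (11.42 ± 1.52 SE, adjusted p = 7.42e-05, to 6601 ± 1302 FPKM), the retinoic acid degrading enzyme Cyp26a1 (9.35 ± 0.26) and Aqp8 (9.26 ± 0.35). Visceral endoderm genes rose in 7 of 17 cases (8 adjusted over the list alone). The visceral endoderm list had a median log2 change of 0.63 and an adjusted p of 0.0023 (adjusted p = 0.146 with an estimated correlation, 1.82e-05 to 0.146 over the alternatives). Visceral endoderm genes included the endocytic receptor Cubn (3.78) and the retinol carrier Rbp4 (2.76). Of 21 parietal endoderm genes, 10 rose and 2 fell (11 and 2 adjusted over the list alone). The parietal endoderm list had a median log2 change of 1.53 and an adjusted p of 0.00521 (adjusted p = 0.377 with an estimated correlation, 6.26e-05 to 0.377 over the alternatives). The retinol transporter Stra6 (7.78), Lama1 (7.07), the fatty acid binding protein Fabp3 (6.96) and Pth1r (6.00) rose most. Epithelial genes rose in 22 of 24 cases (22 adjusted over the list alone). The epithelial list had a median log2 change of 3.80 and an adjusted p of 7.64e-12 (adjusted p = 0.0948 with an estimated correlation, 5.27e-14 to 0.0948 over the alternatives). The keratin Krt8 rose by 7.65 ± 1.01, the adhesion protein Epcam by 6.83 ± 0.56, the tight junction protein Cldn6 by 5.89 ± 0.60 and Cdh1 by 4.70 ± 0.70. Of 21 genes that respond to Wnt signalling, 11 rose (12 adjusted over the list alone). The Wnt target list had a median log2 change of 1.90 and an adjusted p of 0.00291 (adjusted p = 0.336 with an estimated correlation, 0.000121 to 0.336 over the alternatives). Wnt target genes included the feedback inhibitors Notum (5.06) and Axin2 (4.96).

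Part of the pluripotency list was present at day 16: of 38 genes, 12 rose and 1 fell (12 and 1 adjusted over the list alone). As a mean of log2(FPKM + 1), the list stood at 2.51 and 1.96 at day 16 and 0.97 and 0.92 in MEF. XEN cells were near the day 16 level, at 1.86 and 2.13 in CeXEN and 1.64 and 1.67 in eXEN, and ESC far above it, at 6.48 and 6.38. The pluripotency list had a median log2 change of 0.62 and an adjusted p of 0.0226 (adjusted p = 0.177 with an estimated correlation, 1.12e-05 to 0.177 over the alternatives). The list's adjusted p was 0.163 without day 16 replicate 1. Lin28a rose by 5.40 ± 0.37, the RNA-binding protein L1td1 by 5.28 ± 0.46, the Kruppel factor Klf5 by 3.36 ± 0.49, and Sall4 by 4.92 ± 0.33. Pou5f1 stood at 0.379 ± 0.201 FPKM against 0.258 ± 0.0427 FPKM in MEF (0.12 ± 0.28 SE, adjusted p = 0.815), Nanog at 0.309 ± 0.336 FPKM against 0.20 ± 0.0503 FPKM (0.10 ± 0.28 SE, adjusted p = 0.864), and Sox2 at 4.86 ± 4.48 FPKM against 0.878 ± 0.540 FPKM (1.42 ± 0.60 SE, adjusted p = 0.0914). Sox2 passed without day 16 replicate 2 (2.30, adjusted p = 0.0185, 0.0185 to 0.641 over the left-out libraries). Trophoblast genes were higher in 6 of 19 cases (6 adjusted over the list alone). The trophoblast list had a median log2 change of 1.43 and an adjusted p of 0.034 (adjusted p = 0.612 with an estimated correlation, 0.00251 to 0.612 over the alternatives). The list's adjusted p was 0.231 without day 16 replicate 1.

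Fibroblast and mesenchyme genes fell in 28 of 35 cases (29 adjusted over the list alone). The fibroblast list had a median log2 change of -3.06 and an adjusted p of 6.21e-20 (adjusted p = 0.0948 with an estimated correlation, 4.91e-23 to 0.0948 over the alternatives). The collagen cross-linking enzyme Lox fell by 6.82, the proteoglycan Bgn by 6.68 and the matrix protein Postn by 6.48 on the log2 scale, and the pattern recognition protein Ptx3 by 5.82. The surface protein Thy1 was still at 134 ± 62.3 FPKM at day 16 against 306 ± 66.0 FPKM in MEF and did not pass the test (-1.25 ± 0.55 SE, adjusted p = 0.105), though it did with median-of-ratios scaling (-1.56, adjusted p under 0.05). Genes that respond to TGF beta fell in 12 of 23 cases and rose in 2 (12 and 2 adjusted over the list alone). The TGF beta target list had a median log2 change of -1.60 and an adjusted p of 0.000135 (adjusted p = 0.0948 with an estimated correlation, 5.6e-05 to 0.0948 over the alternatives). Macrophage and blood genes, markers of another cell type, fell in 10 of 17 cases (10 adjusted over the list alone). The macrophage and blood list had a median log2 change of -1.77 and an adjusted p of 7.73e-09. The lysozyme Lyz2 fell from 61.4 ± 44.1 FPKM to 0.986 ± 0.720 FPKM. Genes of cell cycle arrest and senescence fell in 8 cases and rose in 3 of 21 (10 and 3 adjusted over the list alone). The cell cycle arrest list had a median log2 change of -1.27 and an adjusted p of 0.00291 (adjusted p = 0.0821 with an estimated correlation, 0.000492 to 0.0821 over the alternatives). Cell cycle arrest genes included the stress-induced gene Gadd45b (-3.16). Chaperone and stress genes fell in 7 of 19 cases (8 fell and 1 rose adjusted over the list alone). The chaperone list had a median log2 change of -0.80 and an adjusted p of 0.00202 (adjusted p = 0.134 with an estimated correlation, 0.000634 to 0.134 over the alternatives). Chaperone genes included the glutathione-degrading enzyme Chac1 (-3.14). Of 35 Hox genes, 6 fell and 1 rose (6 and 1 adjusted over the list alone). The Hox list had a median log2 change of -0.14 and an adjusted p of 0.00714 (adjusted p = 0.651 with an estimated correlation, 0.000181 to 0.651 over the alternatives). Hoxc6 (-2.28) fell most; the list's adjusted p was 0.223 without day 16 replicate 1. Cholesterol synthesis genes fell in 3 cases and rose in 2 of 20 (3 and 2 adjusted over the list alone). The cholesterol synthesis list had a median log2 change of -0.59 and an adjusted p of 0.0171 (adjusted p = 0.717 with an estimated correlation, 0.00891 to 0.717 over the alternatives). The adjusted p was 0.0659 without day 16 replicate 2.

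In all, 2219 genes were higher and 1233 lower at day 16 (64.3% higher), and 789 were lower without day 16 replicate 1. A fit of only these 2 groups gave 0 and 0 (smallest adjusted p = 0.0531), and the replicate number as a block 1212 higher and 760 lower. The median gene was 0.215 higher on the log2 scale as deposited, -0.02 with quantile normalization and 0.013 with median-of-ratios scaling, and these scalings gave 1558 higher and 1758 lower (47.0%) and 1628 higher and 1730 lower (48.5%).

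Signatures chosen by contrasts of the reference groups placed each library between fibroblasts, XEN cells and ESC. The other libraries entered the choice only through the shared estimate of the spread and the filter on low values. The XEN signature, 229 genes higher in eXEN than in both ESC and MEF, was already most of the way to the XEN level at day 12 and stayed there, while the MEF signature was still largely present at day 12 and was lowest at day 28. On a scale where the MEF median is 0% and the eXEN median 100%, the XEN signature stood at 74.8% at day 12, 92.4% and 80.4% in the 2 libraries of day 16, 97.3% at day 20, 88.9% at day 26 and 97.3% at day 28. The MEF signature, 748 genes with ESC at 0% and MEF at 100%, stood at 74.6% at day 12, 43.3% and 56.0% in the 2 libraries of day 16, 31.7% at day 20, 37.4% at day 26 and 10.5% at day 28. The ESC signature, 710 genes with MEF at 0% and ESC at 100%, stood at 19.1% at day 12, 16.9% and 14.3% in the 2 libraries of day 16, 15.3% at day 20, 27.0% at day 26 and 24.6% at day 28. The CeXEN libraries stood at 103.7% and 103.4% of the XEN signature, and the CiPSC lines at 89.7% to 97.4% of the ESC signature. The positions of the cells on the way depend on the processing. The XEN position of day 12 was 64.1% with quantile normalization and 65.7% with a log2 threshold of 1, and that of day 28 was 89.5% and 88.2%. The MEF position of day 12 was 65.7% with quantile normalization and 86.1% with a pseudocount of 0.1, and that of day 26 was 32.4% and 50.5%. With quantile normalization the ESC positions were 2.2% at day 12, 5.9% at day 20, 14.6% at day 26 and 16.1% at day 28, with a pseudocount of 0.1 35.2%, 30.4%, 39.8% and 36.7%, and with a log2 threshold of 1 35.5%, 34.4%, 39.4% and 38.6%. The MEF position of day 28 was 21.6% with that pseudocount and 19.9% with that threshold.

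**Figure D1:**
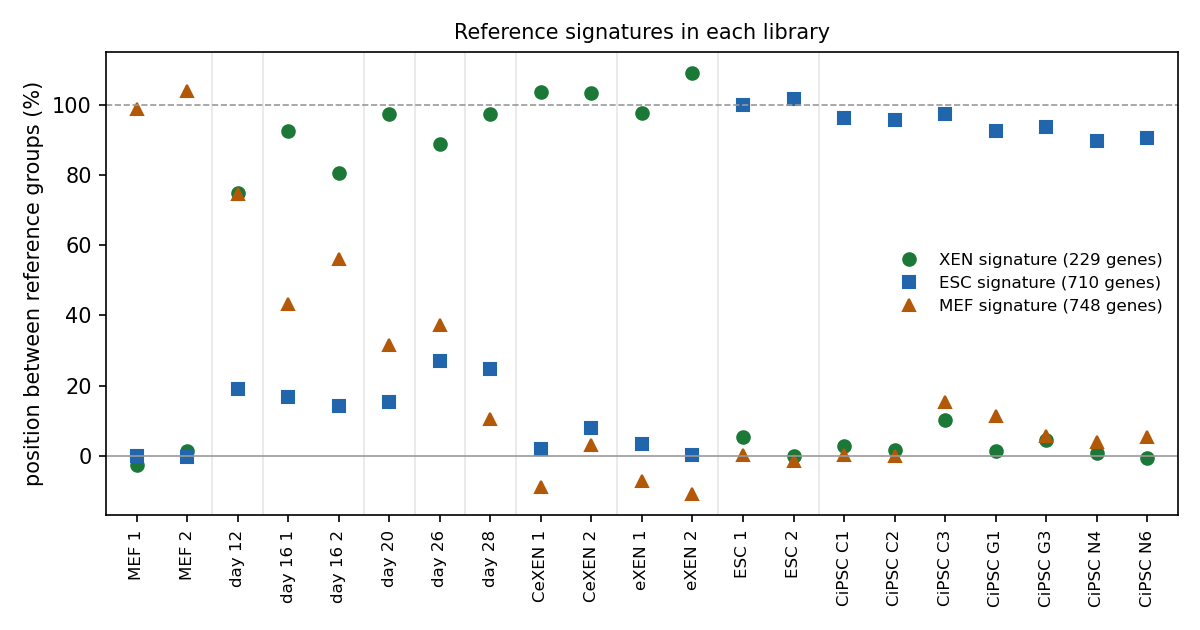
The position of each library (horizontal axis, grouped by sample) on the XEN, ESC and MEF signatures is given in percent of the distance between reference medians (vertical axis), with 1 point per library and no error bars because a point is a single library. The XEN signature stood at 74.8% to 97.3% in the 6 libraries of day 12 to day 28 (64.1% to 92.7% with quantile normalization). The MEF signature lay between 74.6% at day 12 and 10.5% at day 28 (19.9% at day 28 with a log2 threshold of 1 and 21.6% with a pseudocount of 0.1).

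Over the 6 libraries from day 12 to day 28, the question was which genes rose or fell with time. No gene passed the trend over all genes. Fibroblast genes passed as a list, lower late in the series (not with an estimated correlation, adjusted p = 0.488, nor with fry). In single libraries, Pou5f1 and Dppa5a stood highest at day 26, and Sox17 was high throughout. Sox17 stood at 330.3 FPKM at day 12, 599 and 432 at day 16, 513 at day 20, 477 at day 26 and 548 at day 28. Pou5f1 was listed at 0 at day 12, stood at 0.521 and 0.236 FPKM at day 16 and 0.427 at day 20, and reached 18.9 at day 26 and 6.23 at day 28. Dppa5a stood at 13.6, 131, 0.727, 97.2, 558 and 249 FPKM in the same order of libraries. Col1a1 stood at 133 FPKM at day 12, 25.8 and 91.2 at day 16, 6.19 at day 20, 14.7 at day 26 and 1.03 at day 28.

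**Figure D2:**
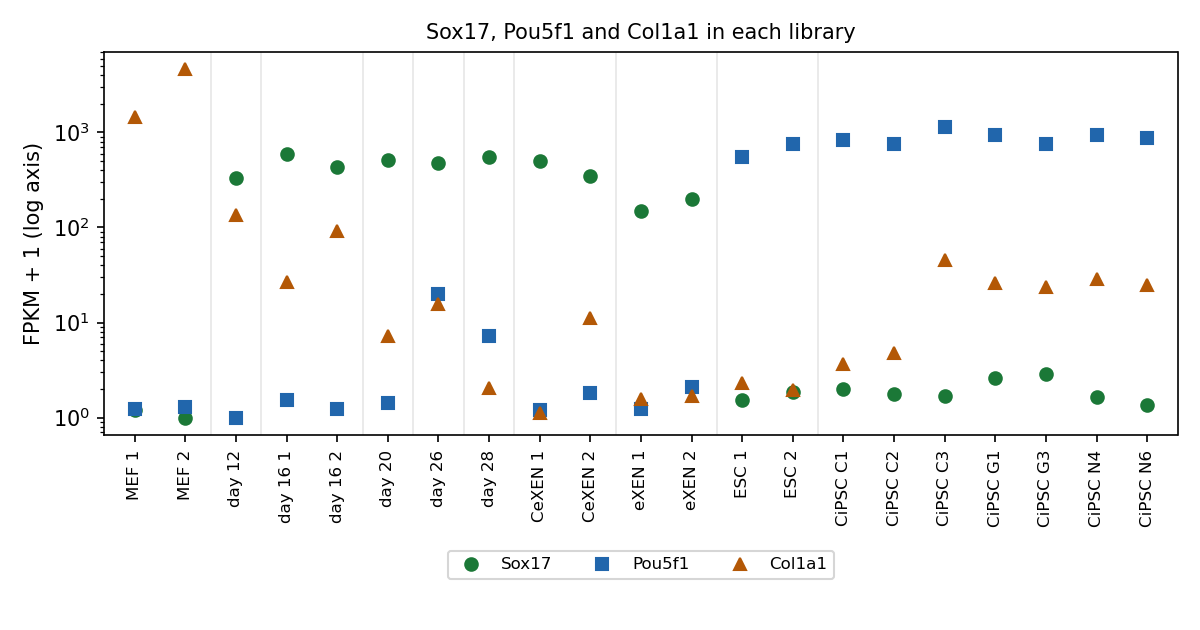
FPKM of Sox17, Pou5f1 and Col1a1 (vertical axis, FPKM + 1 on a log scale) is plotted for every library by group (horizontal axis), 1 point per library. Sox17 was high from day 12 to day 28 and in XEN cells, Pou5f1 was high in ESC and CiPSC, and Col1a1 was high in MEF.

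A linear trend on day passed the test for 0 genes in either direction with limma, with 3349 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.175, and every alternative also gave 0. Leaving out the day 26 library moved the smallest adjusted p to 0.0696 and leaving out day 28 to 0.527. On simulated data the test found 6% of changes of 2 log2 units. Fitted changes over the 16 days were 3.93 ± 0.91 (SE, adjusted p = 0.176) for Pou5f1, 1.43 ± 0.46 (SE, adjusted p = 0.2) for Nanog, -4.70 ± 1.14 (SE, adjusted p = 0.176) for Thy1 and -4.98 ± 1.28 (SE, adjusted p = 0.182) for Col1a1, none past the threshold. As a list, fibroblast genes went down: adjusted over the list alone 28 of 35 fell, over all genes 0 did with limma (29 at an unadjusted p under 0.05). The fibroblast list had a median log2 change of -2.89 and an adjusted p of 4.02e-14 (adjusted p = 0.488 with an estimated correlation, 2.46e-16 to 0.488 over the alternatives). Muscle genes went the same way, 13 of 19 falling adjusted over the list alone and 0 over all genes with limma (15 at an unadjusted p under 0.05). The muscle list had a median log2 change of -2.51 and an adjusted p of 1.08e-08 (adjusted p = 0.454 with an estimated correlation, 1.9e-09 to 0.454 over the alternatives). Pluripotency genes went up, 2 of 38 rising adjusted over the list alone and 0 over all genes with limma (13 higher and 2 lower at an unadjusted p under 0.05). The pluripotency list had a median log2 change of 0.60 and an adjusted p of 0.000147 (adjusted p = 0.454 with an estimated correlation, 0.000157 to 0.454 over the alternatives). In this comparison 14 of the 30 lists passed with the preset correlation and 0 with an estimated one, and the rotation test fry passed 5.

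Day 16 against eXEN asks how cells at day 16 differ from XEN cells of embryonic origin. Of the XEN regulators, Gata4, Foxa2 and Gata6 did not pass the test, while day 16 cells carried more mRNA of many fibroblast, epithelial, imprinted, Hox and retinoic acid genes. Of the 11 lists that passed in this comparison, 0 did so with an estimated correlation and 17 lists passed with fry. Gata4 stood at 413 ± 61.1 FPKM (SD, n = 2) at day 16 and 472 ± 67.4 FPKM (SD, n = 2) in eXEN (-0.19 ± 0.34 SE, adjusted p = 0.76), Foxa2 at 73.1 ± 28.7 FPKM and 109 ± 21.3 FPKM (-0.62 ± 0.26 SE, adjusted p = 0.106) and Gata6 at 70.1 ± 16.2 FPKM and 144 ± 45.9 FPKM (-1.01 ± 0.47 SE, adjusted p = 0.139). Foxa2 passed without day 16 replicate 1 (-1.02, adjusted p = 0.0173, 0.0173 to 0.652 over the left-out libraries), and both day 16 libraries lay below both eXEN libraries for Foxa2 and Gata6. Sox17 was higher at day 16 by 1.57 ± 0.33 (SE, adjusted p = 0.00333), and Crabp1, a retinoic acid binding protein, by 8.57 ± 0.78 (SE, adjusted p = 3.86e-06), with 1075 ± 500.2 FPKM against 2.59 ± 3.41 FPKM.

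Of 20 XEN regulators, 6 rose and 2 fell (6 and 3 adjusted over the list alone), and the list did not differ from other genes (adjusted p = 0.533); its median was -0.05, its mean 0.26 and the direction of its test down, since the test is relative to all genes. Fibroblast genes rose in 25 of 35 cases (28 adjusted over the list alone). The fibroblast list had a median log2 change of 2.77 and an adjusted p of 1.15e-10 (adjusted p = 0.265 with an estimated correlation, 1.02e-12 to 0.265 over the alternatives). The MEF signature stood at 43.3% and 56.0% in the day 16 libraries against -7.1% and -10.9% in eXEN. The fibroblast factor Twist2 rose by 5.57 ± 0.35, the smooth muscle actin Acta2 by 5.83 ± 0.86, Thy1 by 6.59 ± 0.55 and Col1a1 by 4.94 ± 1.20 (adjusted p = 0.0085), whose call was lost without day 16 replicate 2 (4.05, adjusted p = 0.0765). Epithelial genes rose in 19 of 24 cases (19 adjusted over the list alone). The epithelial list had a median log2 change of 3.05 and an adjusted p of 5.89e-08 (adjusted p = 0.265 with an estimated correlation, 1.35e-10 to 0.265 over the alternatives). Epithelial genes included Spint2 (7.05), Epcam (4.69) and Cdh1 (4.39). Hox genes rose in 20 cases and fell in 1 of 35 (23 and 1 adjusted over the list alone). The Hox list had a median log2 change of 1.36 and an adjusted p of 1.75e-09 (adjusted p = 0.265 with an estimated correlation, 1.49e-13 to 0.265 over the alternatives). Hox genes included Hoxa9 (4.28). Imprinted genes, expressed from a single parental allele, rose in 15 of 32 cases (17 rose and 1 fell adjusted over the list alone). The imprinted list had a median log2 change of 1.25 and an adjusted p of 0.000357 (adjusted p = 0.265 with an estimated correlation, 1.74e-06 to 0.265 over the alternatives). The maternally expressed non-coding RNAs Rian (8.47 ± 0.28 SE, adjusted p = 2.31e-10) and Meg3 (7.30 ± 0.36 SE, adjusted p = 9.66e-09) stood at 452 ± 64.9 FPKM and 177 ± 19.8 FPKM at day 16 and 0.305 ± 0.431 FPKM and 0.134 ± 0.109 FPKM in eXEN, and the growth factor Igf2 (6.78) and the Notch ligand homologue Dlk1 (6.08) rose as well. Genes that respond to retinoic acid rose in 11 of 22 cases (12 adjusted over the list alone). The retinoic acid target list had a median log2 change of 1.54 and an adjusted p of 6.94e-05 (adjusted p = 0.265 with an estimated correlation, 5.38e-06 to 0.265 over the alternatives). Retinoic acid target genes included Cyp26a1 (6.68) and Cyp26b1 (5.12). The secreted phosphoprotein Spp1 (6.98) was also among the largest increases.

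Neural genes rose in 10 of 18 cases (10 adjusted over the list alone). The neural list had a median log2 change of 1.11 and an adjusted p of 0.00202 (adjusted p = 0.281 with an estimated correlation, 5.93e-05 to 0.281 over the alternatives). Neural genes included the neurofilament gene Nefm (4.08). Wnt target genes rose in 11 cases and fell in 1 of 21 (13 and 1 adjusted over the list alone). The Wnt target list had a median log2 change of 1.53 and an adjusted p of 0.00367 (adjusted p = 0.45 with an estimated correlation, 0.000366 to 0.45 over the alternatives). Wnt target genes included cyclin D1 (Ccnd1, 5.59). Interferon response genes rose in 8 of 19 cases (8 adjusted over the list alone). The interferon response list had a median log2 change of 0.92 and an adjusted p of 0.002 (adjusted p = 0.469 with an estimated correlation, 6e-05 to 0.469 over the alternatives). Interferon response genes included Ifi27 (4.15), and the adjusted p was 0.0602 without day 16 replicate 1. Genes of cell cycle arrest and senescence rose in 7 cases and fell in 1 of 21 (8 and 1 adjusted over the list alone). The cell cycle arrest list had a median log2 change of 1.26 and an adjusted p of 0.00759 (adjusted p = 0.265 with an estimated correlation, 3.91e-06 to 0.265 over the alternatives). Cell cycle arrest genes included the insulin-like growth factor binding protein Igfbp3 (5.84), and the adjusted p was 0.0512 without day 16 replicate 2. Glycolysis genes fell in 6 cases and rose in 1 of 21 (7 and 2 adjusted over the list alone). The glycolysis list had a median log2 change of -0.92 and an adjusted p of 7.32e-06 (adjusted p = 0.469 with an estimated correlation, 5.06e-07 to 0.469 over the alternatives). Glycolysis genes included the glucose transporter Slc2a3 (-2.46). Cell cycle genes rose in 1 case and fell in 1 of 28 (1 and 1 adjusted over the list alone). The cell cycle list had a median log2 change of -0.18 and an adjusted p of 0.0106 (adjusted p = 0.676 with an estimated correlation, 0.000613 to 0.699 over the alternatives). That call was lost with quantile normalization (adjusted p = 0.15) and without day 16 replicate 1 (adjusted p = 0.26). The genes with the largest decreases at day 16 were the tumour antigen genes Trap1a (-4.92) and Mageb16 (-4.27), the oxidative folding enzyme Ero1l (-4.2), Rp1l1 (-4.15) and the receptor Fgfr3 (-3.53, and -1.87 and no longer called without eXEN replicate 2). Lamb1 (-2.75) and Lin28a (-2.32) were lower at day 16, and the collagen IV chain Col4a1 (3.15) higher.

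In all, 2326 genes were higher and 527 lower at day 16 (81.5% higher), against 1529 higher without eXEN replicate 2 and 343 lower without day 16 replicate 1. With only these 2 groups in the fit the counts were 480 and 53, and with the replicate number as a block 1227 and 255. The median gene was 0.235 higher as deposited, -0.073 with quantile normalization and 0.148 with median-of-ratios scaling, and quantile normalization gave 1349 higher and 1189 lower (53.2% higher).

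CeXEN against eXEN asks whether XEN cells derived from embryos in the chemical medium differ from the established line. The mean and SD of eXEN mix 2 media, of which only that of replicate 1 is the chemical medium, so the group means do not separate origin from medium. Against eXEN replicate 1 alone, in the same medium, the log2 changes were 7.35 for Rian, 6.06 for Meg3, 5.71 for Cldn6 and 4.73 for Col4a1. They were 3.88 for Epcam, 0.97 for Sqle and -4.78 for Lama5, all resting on 1 eXEN library. Gata4, Gata6 and Foxa2 did not pass the test, and the largest increases included imprinted and epithelial genes. Matrix genes went both ways, with Col4a1 at 4.09 and the laminin chain Lama5 at -4.26 on the log2 scale. The parietal endoderm and basement membrane list was not among the 3 lists that passed. Its level was 8.41 and 8.13 in CeXEN, and 7.22 and 8.36 in eXEN replicates 1 and 2. Gata4 stood at 436 ± 7.61 FPKM (SD, n = 2) in CeXEN and 472 ± 67.4 FPKM (SD, n = 2) in eXEN (-0.11 ± 0.34 SE, adjusted p = 0.984), Gata6 at 158 ± 69.8 FPKM and 144 ± 45.9 FPKM (0.10 ± 0.47 SE, adjusted p = 1.0) and Foxa2 at 149 ± 37.7 FPKM and 109 ± 21.3 FPKM (0.43 ± 0.26 SE, adjusted p = 0.383). Rian was 7.69 ± 0.28 (SE, adjusted p = 4.03e-10) higher on the log2 scale in CeXEN, with 261 ± 17.9 FPKM against 0.305 ± 0.431 FPKM, and Meg3 5.96 ± 0.36 (SE, adjusted p = 2.15e-07) higher.

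Of 20 XEN regulators, 2 rose (2 adjusted over the list alone), and the list did not pass its test (adjusted p = 0.841): Ihh rose by 2.78 ± 0.37 (SE, adjusted p = 0.00036), and Sox17 by 1.28 ± 0.33 (SE, adjusted p = 0.0279), a call lost when any of the 4 libraries was left out (1.03 to 1.53, adjusted p = 0.0534 to 0.128). Imprinted genes rose in 10 cases and fell in 1 of 32 (10 and 1 adjusted over the list alone). The imprinted list had a median log2 change of 0.27 and an adjusted p of 0.00176 (adjusted p = 0.988 with an estimated correlation, 0.000132 to 0.988 over the alternatives). Imprinted genes included the cell cycle inhibitor Cdkn1c (5.49). Epithelial genes rose in 5 cases and fell in 1 of 24 (5 and 1 adjusted over the list alone). The epithelial list had a median log2 change of 0.84 and an adjusted p of 0.00408 (adjusted p = 0.988 with an estimated correlation, 0.000521 to 0.988 over the alternatives). Epithelial genes included Cldn6 (6.06) and Epcam (4.99). Cholesterol synthesis genes rose in 4 of 20 cases (4 adjusted over the list alone). The cholesterol synthesis list had a median log2 change of 0.85 and an adjusted p of 0.000395 (adjusted p = 0.988 with an estimated correlation, 0.000227 to 0.988 over the alternatives). The list level was 3.64 in eXEN replicate 2, the library in conventional medium, against 4.90 in replicate 1 and 5.08 and 5.39 in CeXEN, and all 4 genes lost their call without eXEN replicate 2 and without CeXEN replicate 2. The squalene epoxidase Sqle was 2.14 higher, or 0.97 without eXEN replicate 2 and 2.01 without CeXEN replicate 2, and without eXEN replicate 1 it was 3.31 higher. Rps4l (6.73), a retrocopy-like relative of a ribosomal protein gene whose reads may be shared with it and whose value is uncertain, was among the largest increases. The collagen IV chains Col4a1 (4.09) and Col4a2 (3.95), Cyp26a1 (4.32) and Fabp3 (2.80) rose, and the pluripotency marker Zfp42 rose by 3.64 to 13.3 ± 1.59 FPKM. The laminin chain Lama5 fell by 4.26, Rp1l1 by 4.15, the heparan sulfate proteoglycan Gpc4 by 3.70 and Dzip1l by 3.61 on the log2 scale. The small heat shock protein Hspb2 (-3.40) lost its call without CeXEN replicate 2 (-2.72) and without eXEN replicate 2 (-2.67). Pou5f1 stood at 0.518 ± 0.428 FPKM and 0.676 ± 0.623 FPKM (-0.12 ± 0.28 SE, adjusted p = 0.938).

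In all, 668 genes were higher and 409 lower in CeXEN (62.0% higher, and 488 and 492, 49.8%, with quantile normalization). With only these 2 groups in the fit 0 and 0 genes passed (smallest adjusted p = 0.13), and with the replicate number as a block 125 and 75. The counts depended on single libraries as well: 1536 genes were higher and 311 lower without CeXEN replicate 1, 295 and 255 without CeXEN replicate 2, and 317 and 250 without eXEN replicate 2.

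CiPSC against day 16 asks what separates the end product from the replicated time point on the way. Most pluripotency genes were higher in CiPSC, and 16 of 20 XEN regulators were lower while 3 were higher. Pou5f1 stood at 891 ± 129 FPKM (SD, n = 7) in CiPSC and 0.379 ± 0.201 FPKM (SD, n = 2) at day 16, a log2 change of 9.33 ± 0.22 (SE, adjusted p = 1.79e-12), and Nanog at 297 ± 62.9 FPKM and 0.309 ± 0.336 FPKM (7.82 ± 0.23 SE, adjusted p = 1.97e-11). Sox17 stood at 0.998 ± 0.556 FPKM and 516 ± 119 FPKM (-8.04 ± 0.26 SE, adjusted p = 4.42e-11), and Gata4 at 1.40 ± 0.727 FPKM and 413 ± 61.1 FPKM (-7.48 ± 0.27 SE, adjusted p = 7.72e-11).

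Of 38 pluripotency genes, 33 rose and 1 fell (33 and 1 adjusted over the list alone). The pluripotency list had a median log2 change of 4.38 and an adjusted p of 2.81e-20. The transcription factor Utf1 (7.02), Sox2 (5.34) and Dppa5a (7.35, or 4.22 without day 16 replicate 2) rose, and Sall4 rose by 1.71 ± 0.26, while Lin28a missed the size threshold (0.99 ± 0.30 SE, adjusted p = 0.0131) and passed it in some alternatives, such as without day 16 replicate 2 (1.73). Germ cell genes rose in 17 cases and fell in 1 of 22 (18 and 1 adjusted over the list alone). The germ cell list had a median log2 change of 2.38 and an adjusted p of 1.94e-07 (adjusted p = 0.263 with an estimated correlation, 5.21e-09 to 0.263 over the alternatives). Germ cell genes included Dazl (4.11) and the sex-determination factor Dmrt1 (4.12). Two-cell-like genes rose in 14 of 18 cases (15 adjusted over the list alone). The two-cell-like list had a median log2 change of 2.14 and an adjusted p of 2.95e-05 (adjusted p = 0.443 with an estimated correlation, 5.53e-07 to 0.443 over the alternatives). Zscan4f was listed at 0 in both day 16 libraries and stood at 65.7 ± 45.9 FPKM in CiPSC, with its near-identical copies making the value uncertain. The autophagy receptor Calcoco2 was listed at 0 at day 16 and stood at 161 ± 119.9 FPKM in CiPSC. DNA methylation genes rose in 9 cases and fell in 3 of 17 (9 and 3 adjusted over the list alone). The DNA methylation list had a median log2 change of 1.58 and an adjusted p of 0.0014 (adjusted p = 0.139 with an estimated correlation, 1.38e-06 to 0.139 over the alternatives). DNA methylation genes included the methyltransferase cofactor Dnmt3l (6.51) and the hydroxylase Tet1 (4.40). Histone modifiers rose in 13 cases and fell in 2 of 25 (13 and 2 adjusted over the list alone). The histone modifier list had a median log2 change of 1.15 and an adjusted p of 9.85e-05 (adjusted p = 0.0924 with an estimated correlation, 2.27e-06 to 0.0924 over the alternatives). Histone modifier genes included the demethylase Kdm5b (3.17). Glycolysis genes rose in 17 of 21 cases (17 adjusted over the list alone). The glycolysis list had a median log2 change of 1.61 and an adjusted p of 1.43e-05 (adjusted p = 0.376 with an estimated correlation, 5.92e-06 to 0.376 over the alternatives). Glycolysis genes included the enolase Eno1 (2.61). Cell cycle genes rose in 14 of 28 cases (15 adjusted over the list alone). The cell cycle list had a median log2 change of 1.05 and an adjusted p of 4.57e-07 (adjusted p = 0.376 with an estimated correlation, 2.25e-07 to 0.376 over the alternatives). Cell cycle genes included the replication helicase subunit Mcm2 (1.82). Cdh1 rose by 1.89 ± 0.56, but by 0.74 and without a call when day 16 replicate 2 was left out, and by 3.04 without day 16 replicate 1.

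Of 20 XEN regulators, 16 fell and 3 rose (16 and 3 adjusted over the list alone). The XEN regulator list had a median log2 change of -4.72 and an adjusted p of 2.42e-09. The receptor Pdgfra fell by 7.21 and Foxa2 by 6.03. Parietal endoderm genes fell in 17 cases and rose in 1 of 21 (17 and 1 adjusted over the list alone). The parietal endoderm list had a median log2 change of -4.31 and an adjusted p of 4.34e-10 (adjusted p = 0.0597 with an estimated correlation, 1.84e-10 to 0.0597 over the alternatives). Parietal endoderm genes included Pth1r (-7.77) and Col4a2 (-6.55). The largest decreases were S100g (-12.27 ± 1.22 SE, adjusted p = 2.03e-06), Aqp8 (-9.26), Cyp26a1 (-9.03), the homeobox factor Pitx1 (-8.77) and the proteoglycan Srgn (-8.49). Fibroblast genes fell in 24 of 35 cases (27 adjusted over the list alone). The fibroblast list had a median log2 change of -2.13 and an adjusted p of 3.56e-08 (adjusted p = 0.263 with an estimated correlation, 6.02e-10 to 0.263 over the alternatives). Fibroblast genes included Twist2 (-5.59) and Thy1 (-5.36), and Col1a1 stood at 21.3 ± 14.3 FPKM in CiPSC against 58.5 ± 46.2 FPKM (-1.59 ± 0.96 SE, adjusted p = 0.187). Hox genes fell in 22 of 35 cases (22 adjusted over the list alone). The Hox list had a median log2 change of -1.43 and an adjusted p of 3.56e-08 (adjusted p = 0.235 with an estimated correlation, 1.82e-11 to 0.235 over the alternatives). Hox genes included Hoxa9 (-3.91). Retinoic acid target genes fell in 14 cases and rose in 3 of 22 (15 and 3 adjusted over the list alone). The retinoic acid target list had a median log2 change of -1.58 and an adjusted p of 0.00018 (adjusted p = 0.235 with an estimated correlation, 5.63e-07 to 0.235 over the alternatives). Retinoic acid target genes included Crabp1 (-5.34). Cyclic AMP target genes fell in 10 cases and rose in 1 of 18 (10 and 1 adjusted over the list alone). The cAMP target list had a median log2 change of -1.13 and an adjusted p of 0.00417 (adjusted p = 0.0996 with an estimated correlation, 9.6e-08 to 0.0996 over the alternatives). cAMP target genes included the coactivator Ppargc1a, which was at 8.37 ± 0.583 FPKM at day 16 and listed at 0 in CiPSC. Cdkn1c fell by 4.55 and Igf2 by 7.68, both imprinted. Genes of cell cycle arrest fell in 10 cases and rose in 2 of 21 (10 and 2 adjusted over the list alone). The cell cycle arrest list had a median log2 change of -1.06 and an adjusted p of 0.0244 (adjusted p = 0.139 with an estimated correlation, 9.82e-06 to 0.139 over the alternatives). The adjusted p was 0.0782 without day 16 replicate 2.

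In all, 2162 genes were higher and 2823 lower in CiPSC. Among the named genes called in this comparison, the 1 whose sign changed when a library was left out was Txnrd1, which encodes a selenoprotein, with a log2 change of -3.37 that became 0.32 without day 16 replicate 1 and -7.05 without replicate 2. Its FPKM was 15561 in day 16 replicate 1 and 93.0 in replicate 2, and the values of selenoproteins in 4 libraries are uncertain.

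CiPSC against ESC asks whether the induced lines differ from embryonic stem cells. Pou5f1, Nanog and Sox2 did not pass the test, and 3 of the 6 genes higher in CiPSC were maternally expressed non-coding RNAs of the imprinted cluster on chromosome 12. Meg3 stood at 94.6 ± 30.8 FPKM (SD, n = 7) in CiPSC and 14.1 ± 0.00410 FPKM (SD, n = 2) in ESC (2.59 ± 0.29 SE, adjusted p = 0.000853), Rian at 195 ± 42.9 FPKM and 32.9 ± 0.745 FPKM (2.50 ± 0.23 SE, adjusted p = 0.000176) and Mirg at 17.3 ± 3.71 FPKM and 1.91 ± 0.579 FPKM (2.64 ± 0.25 SE, adjusted p = 0.000187). Every CiPSC line was above both ESC libraries for these 3 genes, the lowest CiPSC value of Meg3 being 55.5 and the highest ESC value 14.1 FPKM. They lie in 1 region of mm10 chromosome 12, Meg3 at 109541001 to 109571726, Rian at 109603940 to 109661716 and Mirg at 109729764 to 109749460.

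**Figure D3:**
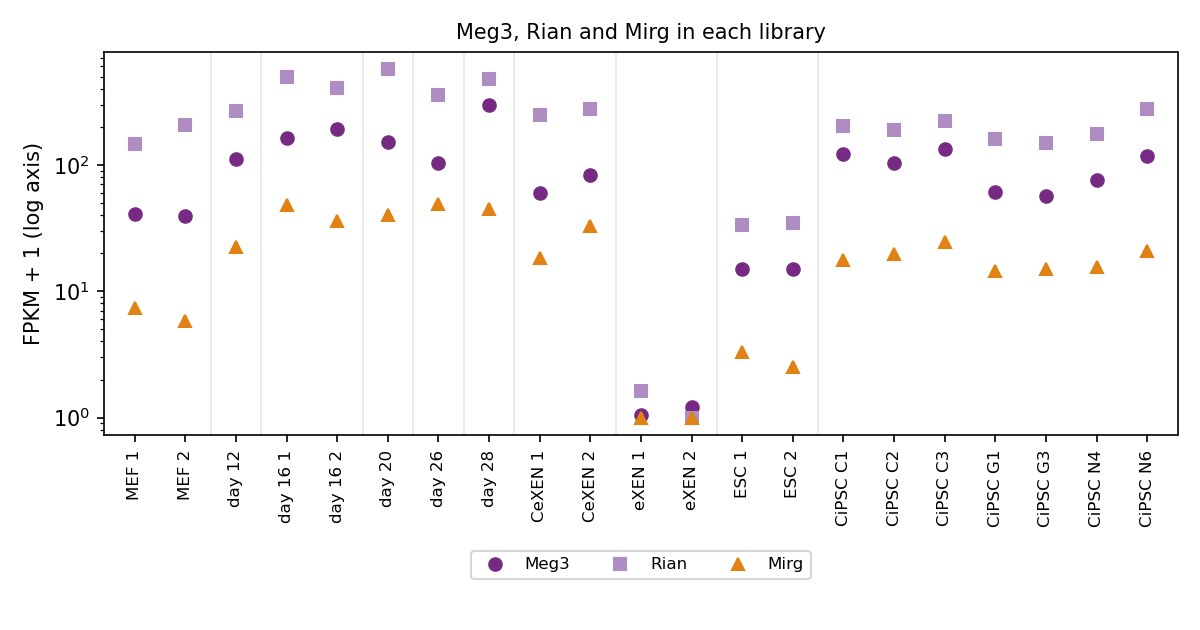
FPKM of Meg3, Rian and Mirg (vertical axis, FPKM + 1 on a log scale) is plotted for every library by group (horizontal axis), 1 point per library. All 7 CiPSC lines lay above both ESC libraries, and eXEN libraries lay near 0 for Meg3 and Rian (0.134 ± 0.109 FPKM and 0.305 ± 0.431 FPKM, SD, n = 2).

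Pou5f1 stood at 891 ± 129 FPKM in CiPSC and 658 ± 146 FPKM in ESC (0.44 ± 0.22 SE, adjusted p = 0.624), Nanog at 297 ± 62.9 FPKM and 433 ± 75.9 FPKM (-0.56 ± 0.23 SE, adjusted p = 0.544) and Sox2 at 199.9 ± 24.8 FPKM and 206 ± 13.9 FPKM (-0.05 ± 0.48 SE, adjusted p = 1.0), none past the test. With limma, 6 genes were higher and 4 lower in CiPSC, and 1412 genes had an unadjusted p under 0.05; without ESC replicate 1 the counts were 35 and 16, and without CiPSC line C2 the lower count was 7. Beside the 3 non-coding RNAs, the higher genes were Vcp-rs (1.63 ± 0.16 SE, adjusted p = 0.000193), Gm15772 (3.11 ± 0.17 SE, adjusted p = 4.29e-07, 779 against 88.6 FPKM, the largest change and the smallest adjusted p) and Gm28635 (2.17), and the lower ones Gm3715 (-1.10), 1700016D06Rik (-1.39), Wdfy4 (-1.54) and Nanog-ps1 (-1.89), of which all but Vcp-rs were named after their values were seen. The 4 lower genes were all low, with mean FPKM of 1.55 to 3.38 in ESC and 0.198 to 0.222 in CiPSC. Vcp-rs, Gm15772 and Nanog-ps1 are related to other genes by sequence and may share reads with them, and the ESC libraries come from different strains, so these values are uncertain. The imprinted list rose as a whole, with 3 of 32 members rising (3 adjusted over the list alone). The imprinted list had a median log2 change of 0.35 and an adjusted p of 0.00344 (adjusted p = 0.765 with an estimated correlation, 0.00499 to 0.765 over the alternatives). Fibroblast genes were higher as a list: over all genes 0 of 35 passed with limma (8 higher at an unadjusted p under 0.05), adjusted over the list alone 1 rose. The fibroblast list had a median log2 change of 0.43 and an adjusted p of 2.03e-05 (adjusted p = 0.854 with an estimated correlation, 1.17e-06 to 0.854 over the alternatives). Col1a1 stood at 21.3 ± 14.3 FPKM against 1.13 ± 0.221 FPKM (2.96 ± 0.96 SE, adjusted p = 0.428), and the MEF signature at -0.1% to 15.3% over the CiPSC lines. C1 and C2 stood at 0.99 and 0.98 on the fibroblast list, the other 5 lines at 1.67 to 2.13, and ESC at 0.91 and 0.85. Germ cell genes were lower as a list: over all genes 0 of 22 passed (6 lower at an unadjusted p under 0.05), adjusted over the list alone 4 fell. The germ cell list had a median log2 change of -0.49 and an adjusted p of 2.03e-05 (adjusted p = 0.854 with an estimated correlation, 5.54e-05 to 0.854 over the alternatives). Lines G1, N4 and N6 carried this, with mean levels of 2.74, 2.26 and 2.25 against 3.35 to 3.5 in the other 4 lines and 3.65 and 3.52 in ESC. Glycolysis genes went up as a list. The glycolysis list had a median log2 change of 0.36 and an adjusted p of 0.00415 (adjusted p = 0.869 with an estimated correlation, 0.00432 to 0.869 over the alternatives). So did chaperone and stress genes. The chaperone list had a median log2 change of 0.35 and an adjusted p of 0.0101 (adjusted p = 0.765 with an estimated correlation, 0.00973 to 0.765 over the alternatives). In both lists 0 members passed with limma over all genes or adjusted over the list alone (1 in each at an unadjusted p under 0.05). The glycolysis levels of C3 (8.29), N4 (7.81) and N6 (7.57) lay above both ESC libraries (7.19 and 6.77), and the other 4 lines at 6.70 to 7.19 lay within or near the ESC range. The 6 measured sex chromosome genes went down as a list. The sex chromosome list had a median log2 change of -0.87 and an adjusted p of 0.0229 (adjusted p = 0.854 with an estimated correlation, 0.0233 to 0.854 over the alternatives). Over all genes 0 passed (1 lower at an unadjusted p under 0.05), and 1 fell adjusted over the list alone. Line C1 stood at 0.04 on this list, the other 6 lines at 1.65 to 2.45, ESC replicate 1 at 3.01 and ESC replicate 2 at 2.26, so C1 and ESC replicate 1 carried much of the difference. Of the 30 lists, 6 passed with the preset correlation, 0 with an estimated one and 0 with fry. Over the comparisons of groups, the list calls that held with an estimated correlation were XEN regulators and macrophage and blood genes for day 16 against MEF, XEN regulators, parietal endoderm and pluripotency for eXEN against ESC, and XEN regulators and pluripotency for CiPSC against day 16.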

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

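The tests of the selenoprotein genes were chosen only after the result was seen. In the CiPSC lines, 51 levels of genes and lists were examined for a line far from the others, by the gap to the nearest line as a share of the whole range, and 4 passed the critical value of Dixon's test, while chance alone sets off about 1 in 20. Line C3 was highest for the interferon response list (a mean log2(FPKM + 1) of 1.75 against 1.23 to 1.36 in the other lines, a gap of 0.75 of the range). It was also highest for the chaperone and stress list (5.68 against 5.04 to 5.21, a gap of 0.73) and for the endoderm factor Gata6 (2.26 against 0.43 to 1.18 on the log2 scale, a gap of 0.59), and had the lowest depth (0.4 times that of ESC replicate 1). Line C1 was lowest for the sex chromosome list (0.04 against 1.65 to 2.45, a gap of 0.67), and the Y-linked gene Uty was listed at 0 in C1 and at 3.32 to 4.74 FPKM in the others.

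A status of low data was given to 446 genes in each of 4 libraries (day 12, day 16 replicate 1, day 20 and day 26), to the same number each time, and to 0 genes in the other 17 libraries, a signal in a column that the comparisons do not use. Of these genes, 57 were tested. The 4 libraries also listed genes with an annotated selenocysteine far higher than day 16 replicate 2 and day 28: the FPKM of Txnrd1 was 14928 at day 12, 15561 in day 16 replicate 1, 18929.7 at day 20 and 18725 at day 26, against 93.0 in day 16 replicate 2 and 45.3 at day 28. Over 23 such genes the FPKM per fragment was higher in the 4 libraries by a median of 7.15 on the log2 scale (quartiles 4.21 and 10.09), against -0.04 over 15027 other genes, so a candidate explanation is that the quantifier handled these genes differently. The fragments behind these genes were fewer in the 4 libraries (median -2.94, quartiles -5.1 and -1.21). Both measures take the fragments from the bounds of the same quantifier, which may be affected too. They therefore cannot decide whether the cells held more selenoprotein mRNA. What differed between the runs of the quantifier stays open, and the values of these genes in these libraries are uncertain.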

How the results depend on the processing

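The restriction to long coding genes, the fibroblast covariate, the 2 further fits of the trend, and list tests with a replicate block or without single day 16 libraries were chosen only after the result was seen. Counts of genes not listed here stayed within 1.5 times the reported ones. With only the 2 groups compared, day 16 against MEF gave 0 higher and 0 lower genes with limma, eXEN against ESC 996 higher, day 16 against eXEN 480 higher and 53 lower, CeXEN against eXEN 0 and 0, and CiPSC against ESC 18 lower. With 2 libraries per group such a fit has fewer residual degrees of freedom, and its spread comes from those groups alone. In eXEN against ESC, also with 2 libraries per group, 996 higher and 2256 lower genes still passed. Fewer degrees of freedom alone therefore do not account for the 0 calls. At an unadjusted p under 0.05 the comparisons with 0 calls had 4062 and 2184 genes. The replicate number as a block, although the numbers do not pair (correlations of -0.12 to 0.05), gave 1212 higher and 760 lower for day 16 against MEF, 1227 and 255 for day 16 against eXEN, and 125 and 75 for CeXEN against eXEN, with fewer residual degrees of freedom. Quantile normalization gave 1349 higher and 1189 lower for day 16 against eXEN, and the median gene moved from 0.235 to -0.073. For CiPSC against ESC, the lower genes numbered 1 with a pseudocount of 0.1, 8 with no filter on low values and 0 with a filter at FPKM 5 (1091 genes at an unadjusted p under 0.05). Long protein-coding genes without selenocysteine gave 0 higher and 2 lower (1047 genes at an unadjusted p under 0.05), the non-coding RNAs being left out by construction. The 4 lower genes had mean FPKM of 1.55 to 3.38 in ESC, under that filter. The filter counts libraries of all groups, so whether it removed these genes was not tested. With the fibroblast level as a covariate the counts were 4 higher and 4 lower, and Meg3 lost its call at a log2 change of 2.84 (adjusted p = 0.162, against 0.000278 to 0.0365 over its other alternatives), in a fit of 2 groups alone. For the trend, all alternatives gave 0 genes with limma (3349 genes at an unadjusted p under 0.05 as reported).

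Leaving out single libraries gave 789 to 1353 lower genes for day 16 against MEF, 1529 to 2522 higher and 343 to 613 lower for day 16 against eXEN, 295 to 1536 higher and 250 to 489 lower for CeXEN against eXEN, and 5 to 35 higher and 4 to 16 lower for CiPSC against ESC. The lowest and highest came without day 16 replicate 1 and MEF replicate 1, without eXEN replicate 2 and eXEN replicate 1 (higher), without day 16 replicate 1 and eXEN replicate 1 (lower), without CeXEN replicate 2 and CeXEN replicate 1 (higher), without eXEN replicate 2 and eXEN replicate 1 (lower), and, at the high end of CiPSC against ESC, without ESC replicate 1. Among named genes past the threshold, the 1 that changed sign was Txnrd1 in CiPSC against day 16, from -7.05 without day 16 replicate 2 to 0.32 without day 16 replicate 1. For named genes over all alternatives, 7504 values stayed on their side of the threshold, 847 lost it and 10 gained it. Of called named genes, 78 of 106 held in every leave-out for day 16 against MEF, 80 of 110 for eXEN against ESC, 66 of 98 for day 16 against eXEN, 26 of 71 for CeXEN against eXEN, 105 of 122 for CiPSC against day 16 and 4 of 4 for CiPSC against ESC. Of 72 list calls with the preset correlation, an estimated correlation gave 7, since members of a list vary together; quantile normalization gave 77 and the pseudocount 72. The 87 calls of fry answer another question, since it tests a list against no change and camera tests it against the other genes. The number of signature genes moved with a threshold of log2 1 to 619 (XEN), 2078 (ESC) and 1515 (MEF), as the looser threshold admits more genes, and with a pseudocount of 0.1 to 1588 (ESC) and 1166 (MEF). Of positions of libraries on signatures, 71 moved by more than the spread and 64 did not, and of list levels 53 moved and 64 did not. Depth limits low genes most: it ranged from 0.4 to 1.58 times that of ESC replicate 1.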

Other observations

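The tests of the day 16 libraries, of scaling, of the corrected ESC-like share and of the whole ESC profile were chosen only after the result was seen, and the other 2 before. Day 12 had the highest level of several groups of genes among the 6 libraries of the time course, given as mean log2(FPKM + 1) per list in single libraries. Interferon response genes stood at 3.87 at day 12, 1.52 and 2.42 in MEF and 1.75 to 2.46 in the 5 later libraries. Genes of hepatocytes and gut endoderm stood at 2.11 at day 12, 0.18 and 0.38 in MEF and 0.74 to 1.55 in the 5 later libraries. Muscle genes stood at 3.12 at day 12, 1.13 and 2.77 in MEF and 0.61 to 2.30 in the 5 later libraries. Wnt target genes stood at 3.64 at day 12, 1.40 and 1.67 in MEF and 2.74 to 3.32 in the 5 later libraries.

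Among the CiPSC lines, N4 and N6 held less mRNA of two-cell-like genes, at 1.33 and 1.31 against 3.40 to 4.04 in the other 5 lines and 3.5 and 2.62 in ESC. Germ cell genes stood at 2.26 in N4, 2.25 in N6 and 2.74 in G1, against 3.35 to 3.5 in the other 4 lines. The pluripotency list stood at 6.35 to 6.65 over all 7 lines.

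The 2 libraries of day 16 differed in a set of 68 genes, 39 of them protein-coding, with an FPKM of at least 20 in replicate 1 and at least 8-fold less in replicate 2 (median -4.62 on the log2 scale), chosen after their values were seen. Among them were genes of stomach epithelium: Gkn1 stood at 158.8 FPKM in replicate 1 and 3.74 in replicate 2, and Pgc at 519 and 12.7. The processing set is argued against as the whole cause, since day 28, processed like replicate 2, was higher than replicate 2 by a median of 3.78 (quartiles 2.27 and 4.64). Choosing genes that are low in replicate 2 partly sets the median of -4.62 and favours other libraries lying above replicate 2, so 3.78 may be overstated. Replicate 2 held more fibroblast mRNA (MEF signature at 56.0% against 43.3%, list level 4.30 against 3.51), but more remaining fibroblasts are argued against as the whole cause, since genes of the XEN signature were lower there by a median of only -0.41 (quartiles -0.99 and 0.06, 229 genes). A difference in the cells of the 2 samples stays open, and loci in the set with near-identical profiles, such as Slc38a6 and clone loci, may share reads and are uncertain.

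Fibroblast genes were higher in CiPSC than in ESC as a list with the preset correlation alone (adjusted p = 0.854 with an estimated one and 0.789 with fry, and 0 of 35 genes called), while C1 and C2 lay near ESC, and RNA from fibroblasts in the same culture is a candidate explanation that the tables leave open. Of 114 genes of the MEF signature with an FPKM of at least 100 in MEF, 86.0% stood above their ESC level, but the share of the MEF level ranged from 0.3% to 2.08% between quartiles (a ratio of 6.82), which lies between the bounds set for and against it. The genes were chosen partly for low values in the same ESC libraries, which favours CiPSC values above ESC. In C1 and C2, which lay near ESC on the list, 64.0% and 62.3% of the genes stood above their ESC level. The median share was 0.0831% in line C1, 0.0565% in C2, 1.46% in C3, 1.89% in G1, 0.576% in G3, 0.817% in N4 and 0.756% in N6, and 1.14% for Acta2 (line G1 at 138 FPKM, the other 6 at 11.2 to 41.2), 0.659% for Col1a1 and 1.91% for Lgals1, which are among the most abundant of these genes in MEF. Scaling between libraries is argued against, since 2991 other genes at the ESC level of the list moved by a median of 0.02 (quartiles -0.16 and 0.21), against 0.43 over the list. Some differentiating cells in the CiPSC cultures stay open as another source, untested.

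Pou5f1 was at 18.9 FPKM at day 26 and 6.23 at day 28, and a small share of ESC-like cells might account for this. At day 26 Pou5f1 rose from day 20 by 2.81% of its ESC level, and 51.5% of 132 abundant ESC signature genes rose by at least the preset part of that share, just past the bound of 50% set before, but 4 genes stood at or above their ESC level before, and the step from day 16 replicate 1 to day 20 as a control gave 34.1%. A corrected version, defined after that was seen, gave 52.0% of 125 genes with 32.8% in the control step, above the 25% it allowed. Cells with the whole ESC profile at that share are argued against: 22 abundant protein-coding ESC genes with an FPKM under 1 before rose by a median of 0.0271% of their ESC level (quartiles -0.00386% and 0.924%), with Utf1 at 0.219% and Fgf4 listed at 0, though Dppa2 at 1.07% and Dppa4 at 2.57% lay nearer to Pou5f1. Cells with part of that profile stay open.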
